A study of Nicotiana tabacum with 40 samples.

How the data were processed

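Small RNA libraries were compared from tobacco BY-2 cells, a fast-growing suspension line of Nicotiana tabacum, that expressed AGO1 fused to GFP. Per the labels, the cells were synchronised with aphidicolin, an inhibitor of DNA polymerase, and sampled in S, G2, M and G1 phase. For each phase there were 5 libraries of total RNA and 5 of RNA from an immunoprecipitation (IP) of AGO1 with a single-domain antibody against GFP, 40 libraries in all. The labels give the fraction, the phase and the replicate number of each library. They do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The titles also hold a number for each phase that rises from S to G1, without a unit. A difference between phases therefore cannot be told apart from one in the time of sampling after the synchronisation. Per the labels' protocols, RNA was extracted with Trizol and chloroform and the libraries were made with the TruSeq Small RNA kit. The steps of the IP are not given in the sources used here.

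The deposited files hold raw read counts, as the values show: each lists every distinct sequence of a library, of 18 to 34 nt, with the count of its reads, and is not normalised. The submitters' processing notes name FastQC, Trimmomatic and Bowtie. Their versions, their roles and a genome build are not given in the sources used here. No replicates were pooled in the files. No genome was used here, so a tag (a distinct sequence with its count) was reported by its sequence and has no position or gene, and reads shared between near-identical loci could not be divided. The T of the files stands for U of the RNA.

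The libraries held 2135711 to 66205171 reads. Replicates 1 to 3 held 15831359 to 24386133 reads in total RNA and 2135711 to 23818853 in the IP, and replicates 4 and 5 held 46603536 to 66205171 and 34122452 to 60918493. The share of reads with an undetermined base also separated them, at no more than 0.000796% in replicates 1 to 3 and at least 0.00214% in replicates 4 and 5, and they were therefore treated as 2 sequencing batches. The labels name no batch. Shares of reads in single libraries were given Wilson 95% intervals, the widest of which reached 0.0769 percentage points to either side. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of replicates agreed within sampling noise: the chi-square statistic per degree of freedom over tags with at least 50 reads was 6.61 or more.

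Reads of 18 to 28 nt were analysed. Before the data were examined, 127 sequences under 86 names were listed: 45 miRNA families with known targets (silencing machinery, auxin, development, nutrient and copper, immune receptors and others), 16 passenger strands, 20 tRNA 5′ starts and, as a control for RNA of another organism, 5 animal miRNAs. Tags that shared their first 18 nt with a listed sequence were summed under its name. Each other tag was a feature of its own. Features at 5 counts per 1000000 reads (CPM) or more in at least 5 libraries of a fit were tested, and a listed name was called measured at a mean of 10 CPM or more in at least 1 group. Library sizes were the reads of 18 to 28 nt. A 5.8S rRNA sequence of 123 nt was used to measure the share of reads that matched it.

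Tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with Benjamini-Hochberg adjustment, and a feature was called at an adjusted p under 0.05. Standard errors of log2 ratios were derived from the F statistic. IP and total RNA were compared in 1 fit of all 40 libraries scaled by library totals, since the IP changes most features at once. This fit also gave the test of whether the difference between IP and total RNA depended on the phase. Phases were compared in separate fits of the 20 total RNA and the 20 IP libraries with TMM factors, over all 4 phases and between neighbouring phases. Shares of read lengths and of a first U were compared with exact two-sided permutation tests of 5 against 5 libraries, where the smallest possible p is 0.0079, adjusted over 40 tests, and neighbouring phases also with a paired sign-flip test. Listed families were also adjusted over the list alone. Besides listed names, the text names the 5 tags with the largest rise and the 5 with the largest fall per comparison among those called, with a mean of at least 50 CPM in the higher group and no overlap between the libraries compared. These rules, the lists and the main alternatives were fixed before the data were examined, and tags named outside the rule are marked as such.

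The replicate numbers are shared by all groups. Whether they pair the libraries was checked by correlating the deviations from the group means of libraries with the same number. All 5 correlations were over 0.1 for G2 against S in total RNA (lowest 0.304) and for the 3 comparisons of neighbouring phases in the IP (lowest 0.182), so the value with the replicate number as a block is given there where it differs. For the other comparisons at least 1 correlation was under 0.1.

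The fits were tested on simulated counts with 200 changed features each. They were drawn from the mean of each feature over all libraries of the fit, the trended dispersions and the real library sizes. IP and total RNA thus shared a mean, and libraries were drawn independently, without the correlation between replicates. Recovery in the real data may therefore differ. A 4-fold change was recovered for 47% to 69% of changed features in the total RNA phase comparisons, 71% to 89% in the IP phase comparisons and 80% between IP and total RNA. A 2-fold change was recovered for 2% to 7% of changed features in the phase comparisons and for 61% between IP and total RNA. The test of phase dependence recovered 2% of 4-fold changes. DESeq2 1.42.0, TMM or library totals, a filter at 1 CPM, tags of 20 to 24 nt, exact family sequences, the replicate block, each batch alone and leaving out each replicate number were tried as alternatives. A batch term, leaving out 4 IP libraries of low depth or with animal miRNA reads (G2 replicates 1 and 2, M replicate 2, G1 replicate 2) and leaving out the total RNA library of S replicate 5, which had the highest share of 5.8S rRNA, were added after the data were seen, as was the paired test of shares. Tags more than 100-fold higher in the IP than in total RNA are given by number, without their sequence, because they may not be of tobacco. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used for the share tests and the plots.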

Results

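ARGONAUTE 1 (AGO1) is the main effector of miRNAs in plants, and the study addresses its regulation and function over the cell cycle. Small RNAs were sequenced from total RNA and from an AGO1 IP of synchronised tobacco BY-2 cells in S, G2, M and G1 phase, with 5 libraries per fraction and phase. The libraries held 2135711 to 66205171 reads. The IP libraries of G2 replicates 1 and 2 and of M replicate 2 were the shallowest, with 1578049, 4745193 and 2328372 reads of 18 to 28 nt. All levels are counts per 1000000 reads of 18 to 28 nt (CPM), as mean ± SD.

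AGO1 IP RNA differed from total RNA in length and in first base. Total RNA was rich in 24-nt reads, the size class of heterochromatic siRNAs in plants, whereas the IP was rich in 21- and 22-nt reads that began with U. Reads of 24 nt made up 33.7% ± 5.37 of total RNA and 6.06% ± 1.10 of the IP (SD, n = 20 each). Reads of 21 nt made up 14.4% ± 1.40 and 34.2% ± 4.58, and reads of 22 nt 23.1% ± 2.98 and 45.2% ± 6.01. A first U was found in 26.1% ± 1.41 of total RNA reads and in 88.2% ± 10.3 of IP reads. The preference held within each length: U began 40.9% of 21-nt reads in total RNA and 90.5% in the IP, 37.7% and 92.9% of 22-nt reads, and 15% and 87.3% of 24-nt reads. A began 63.4% of 24-nt reads in total RNA and 4.70% in the IP.

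In each of the 4 phases, the libraries of the IP and of total RNA did not overlap in any of these 4 shares (exact permutation test, p = 0.0079 in 16 of 16 tests, the smallest possible, adjusted p = 0.0198, n = 5 each). The difference for 21-nt reads was 16.7 percentage points in replicates 1 to 3 and 24.3 in replicates 4 and 5, and that for a first U was 59.2 and 66.6. Between neighbouring phases of a fraction, 0 of 24 exact permutation tests passed adjustment and 0 had an unadjusted p under 0.05. The first U share was 79.4% ± 17.5 in the IP of G2 against 91.9% ± 0.940 in that of S (n = 5 each), a difference within the spread of the G2 libraries (exact permutation test, p = 0.278). With the replicate number as a pair, the 22-nt share was higher in 5 of 5 pairs in G2 than in S of total RNA (by 2.02 percentage points ± 2.21), in M than in G2 of the IP (5.88 ± 7.56) and in G1 than in M of the IP (3.83 ± 4.00). An exact sign-flip test of 5 pairs cannot fall under p = 0.0625, the value of each, and 0 of 24 such tests passed (adjusted p = 0.429 at the lowest).

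**Figure D1:**
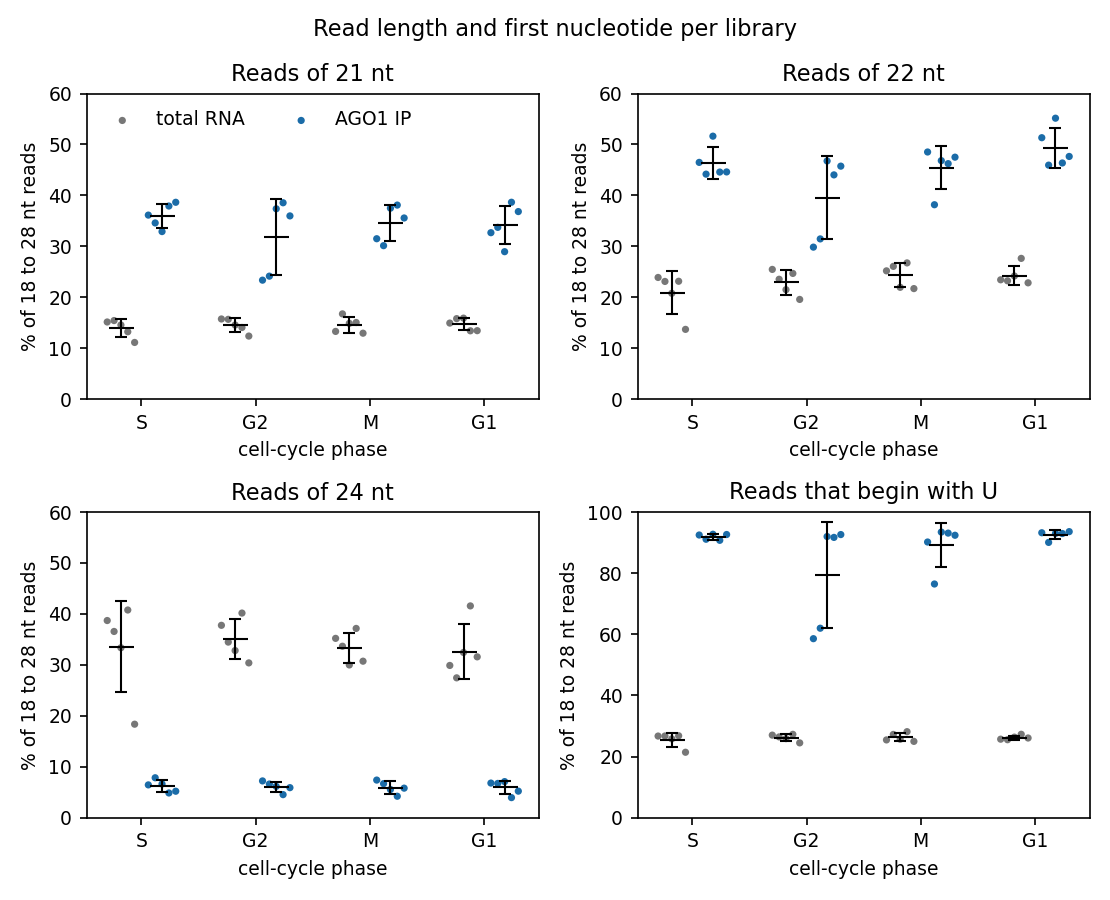
Share of reads of 21, 22 and 24 nt and of reads that begin with U, in percent of the reads of 18 to 28 nt, for each library of total RNA (grey) and of the AGO1 IP (blue) by cell-cycle phase. Points are libraries, and bars give the mean and SD of 5 libraries; first U shares average 26.1% in total RNA and 88.2% in the IP.

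Scaled by library totals, most measured miRNA families were enriched in the AGO1 IP. This was not particular to the listed families: all tested tags with a first U had a median log2 ratio of 2.43, and 85.0% of them were called higher. Of 45 listed families, 20 were measured, and 18 of these were higher and 2 lower in the IP (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, over all features and adjusted over the list alone), although with the size factors of DESeq2 8 were called higher and 5 lower, and 7 of the 18 had a ratio below 0. The most abundant was miR166, which targets HD-ZIP III transcription factors, at 19901 ± 5866 CPM in the IP and 3909 ± 1733 in total RNA (n = 20 each). Of the 2 lower families, miR390 fell further. This miRNA directs the processing of the TAS3 transcript and is known to load into AGO7. It fell from 1141 ± 277 CPM in total RNA to 185 ± 33.7 in the IP, a log2 ratio of −2.63 ± 0.13 (SE; adjusted p = 1.2e-20, and −4.77 with the size factors of DESeq2).

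Among families that target the silencing machinery, 3 of 3 were higher by the library totals. miR162, which targets DCL1, rose 9.29-fold (log2 ratio 3.21 ± 0.15 SE), and miR403, which targets AGO2, rose 8.17-fold (3.02 ± 0.18). The size of these and the following ratios depends on the scaling: the size factors of DESeq2 shifted the log2 ratios of all features by a median of −2.23. miR168, which targets AGO1 itself, was at 3105 ± 970 CPM in the IP and 1461 ± 417 in total RNA (log2 ratio 1.09 ± 0.17), and its ratio turned to −1.02 with the size factors of DESeq2. In the development list 6 of 6 measured families were higher, among them miR159 (GAMYB-like factors; 2.66 ± 0.19), miR319 (TCP factors; 3.32 ± 0.27), miR171 (GRAS proteins; 2.88 ± 0.25) and miR396 (growth-regulating factors; 2.55 ± 0.18), with miR156 at 2.17 ± 0.13 by library totals and −0.01 with DESeq2.

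In the auxin list 3 of 4 measured families were higher and miR390 lower. The siRNA tasiARF, which arises from TAS3 and targets ARF3 and ARF4, had a log2 ratio of 2.53 ± 0.22, and miR167 and miR393 had ratios of 2.02 ± 0.16 and 1.91 ± 0.15 that turned to −0.17 and −0.30 with DESeq2. In the nutrient and copper list 4 of 4 were higher, with miR408 at 3.50 ± 0.39 and miR827 at 2.27 ± 0.26, while miR398 (2.20 ± 0.22) and miR397 (1.00 ± 0.33) turned to −0.04 and −1.43 with DESeq2. Of the immune receptor list, 2 of 11 families were measured: miR6019, a 22-nt miRNA of tobacco, had a ratio of 2.19 ± 0.19 (−0.10 with DESeq2), and miR6020 one of −0.52 ± 0.22 (adjusted p = 0.023). The remaining list held miR4376, at 3.03 ± 0.14.

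Of 2 measured passenger strands 1 was lower in the IP, and of 11 measured tRNA 5′ starts 11 were. The passenger strand of miR168 fell from 69.4 ± 37.6 to 1.01 ± 0.501 CPM (log2 ratio −6.00 ± 0.26). That of miR390 was not called over the mean of the 4 phases, at 35.7 ± 8.73 and 50.7 ± 57.2 CPM (log2 ratio 0.30 ± 0.28, adjusted p = 0.293). In S alone it was called higher, at 36.4 ± 12.4 CPM in total RNA and 99.9 ± 89.7 in the IP, and it was not called in G2, M or G1. A difference between phases was not shown: the edgeR test of phase dependence called 0 of the 2 passenger strands (lowest unadjusted p = 0.114). That test recovered 2% of simulated 4-fold changes. The tRNA 5′ starts fell by log2 ratios from −2.20 ± 0.23 for tRNA-Tyr to −6.14 ± 0.38 for tRNA-Ala. Within replicates 1 to 3, 18 families were higher and 2 lower; within replicates 4 and 5, 18 were higher and 1 lower.

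**Figure D2:**
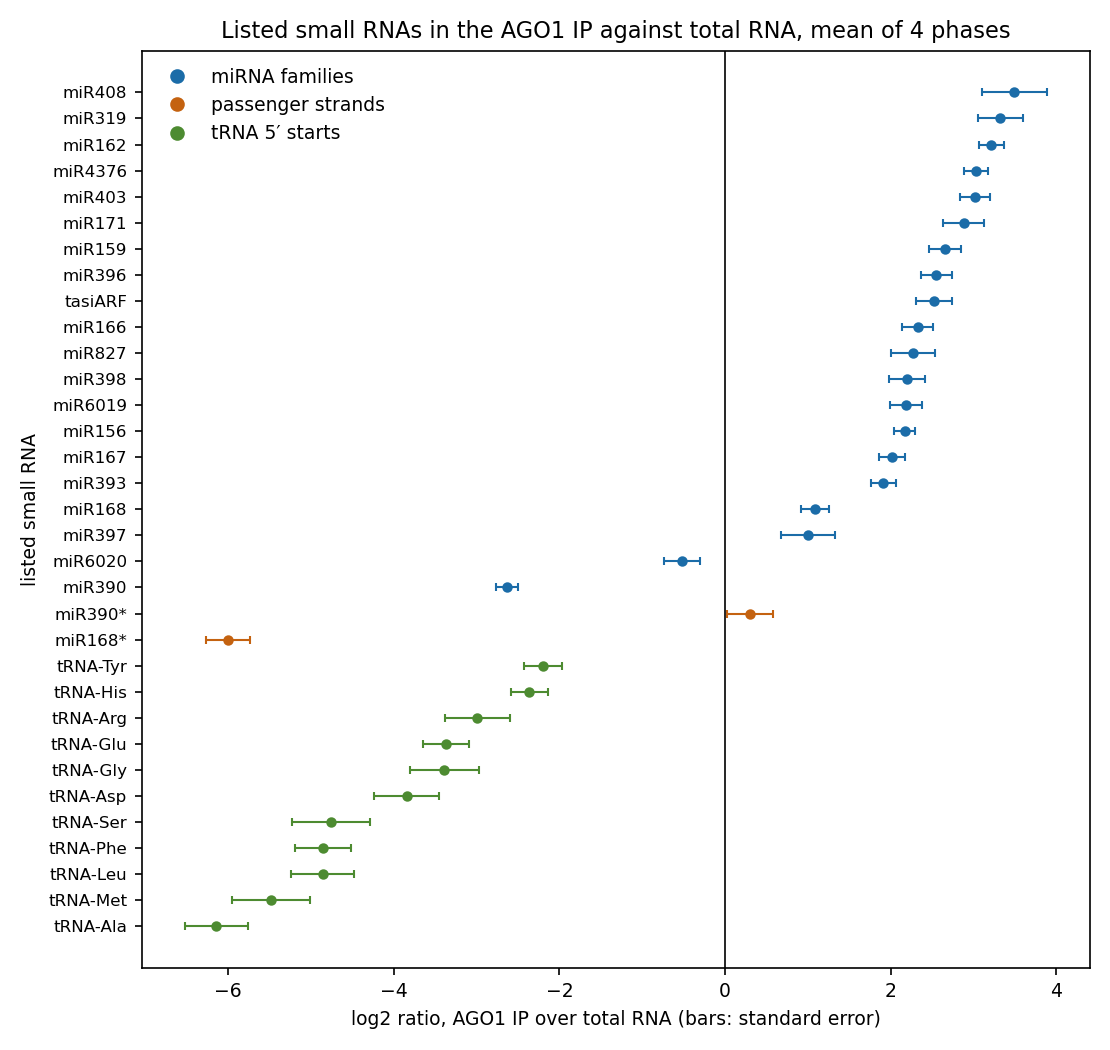
Log2 ratio of the AGO1 IP over total RNA for each measured listed small RNA, averaged over the 4 phases and scaled by library totals; bars are standard errors. miRNA families (blue) run from −2.63 for miR390 to 3.50 for miR408, and the 11 tRNA 5′ starts (green) lie at −2.20 or below; with the size factors of DESeq2, miR156, miR167, miR168, miR393, miR397, miR398, miR6019 and the passenger strand of miR390 turn to below 0.

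Over all features, 38207 of 38790 were called between IP and total RNA, 18539 of them higher and 19668 lower in the IP, or 48.5% higher. A tag could enter this fit through 1 fraction alone, and the separate fits tested 23697 features in total RNA and 19919 in the IP. The share called, the split of directions and the counts by first base below therefore depend on the filter too. With the size factors of DESeq2, which lowered the median log2 ratio of all features from −0.93 to −3.17, 32749 were called, of which 9415 were higher and 23334 lower, or 28.7% higher; TMM lowered the median to −1.04 and called 38167. The calls followed the first base and the length: 17758 of 20882 tags with a first U were higher, against 188 of 7499 with a first A, 475 of 6876 with a first C and 98 of 3494 with a first G. Of 22-nt tags with a first U 9660 of 9955 were higher, and of 24-nt tags with a first A 6 of 2660. Of 24-nt tags with a first U 685 of 1384 were higher and 562 lower.

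The 5 tags with the largest rise, of 24 to 28 nt, are numbered here without their sequence because they may not be of tobacco. The highest of them, a 27-nt tag, was at 1228 ± 875 CPM in the IP and 0.437 ± 0.167 in total RNA. The 5 tags with the largest fall overlapped one another, and their origin was not tested. CAGTTAAAAAGCTCGTAGTTGGACT fell from 127 ± 105 to 0.131 ± 0.173 CPM (log2 ratio −10.65 ± 0.48, adjusted p = 4.5e-22). Within replicates 1 to 3, 32671 of 33228 features were called, and within replicates 4 and 5, 25040 of 25773.

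The direction of the listed families in the IP was compared phase by phase. Of the 20 measured families, 18 were higher and 1 lower in S, and 17 were higher and 1 lower in each of G2, M and G1. No feature passed the edgeR quasi-likelihood test of phase dependence: 0 of 38790 were called, with 2090 at an unadjusted p under 0.05, while DESeq2 called 538. This test recovered 2% of simulated 4-fold changes, so even 4-fold changes went largely undetected, and a count of 0 does not show that the phases were alike.

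In total RNA a small group of tags was highest in G1 or M, where phase and time of sampling cannot be told apart. Over the 4 phases 31 of 23697 features were called, and 25 of them were highest in G1 and 6 in M. The 24-nt tag AGTACGTTCTGATTGCCATCGGTT rose from 8.48 ± 3.17 CPM in S to 61.02 ± 15.03 in G1 (n = 5 each; adjusted p = 0.0017, edgeR quasi-likelihood test), by 6.17-fold within replicates 1 to 3 and 10.1-fold within replicates 4 and 5. The 21-nt tag TCTTGGCTTTGCAATGTTGGC rose from 13.0 ± 5.96 CPM in G2 to 59.6 ± 7.58 in G1 (adjusted p = 0.025). For both tags the adjusted p is that of the test over the 4 phases. The phases printed are the lowest and highest of the tag, and that pair was not tested. Without a genome, none of these tags could be assigned to a gene.

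No listed family was called by phase in total RNA: 0 of 17 measured families passed over all features or adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0. miR168 was at 1460 ± 609 CPM in S, 1565 ± 450 in G2, 1456 ± 311 in M and 1365 ± 363 in G1. Mean levels of miR398, which targets copper superoxide dismutases, were 1117 ± 624 CPM in S and 608 ± 287 in G1. Within replicates 1 to 3, 27 features were called by phase, of which 13 were higher in G1 than in S; within replicates 4 and 5, 0 of 13766 were called by edgeR and 15 had an unadjusted p under 0.05. Leaving out any one of replicate numbers 1 to 4 left 2 to 6 calls.

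Between neighbouring phases of total RNA, M against G2 gave the only calls, 3 of 23697 features, each higher in M. They lie outside the rule for named tags and were chosen after their values were seen. ACGCTGACTGGCGCATTGAGCAACT rose from 1.95 ± 0.603 to 15.3 ± 2.93 CPM (adjusted p = 0.0072), GCACACTCTGGATGAAAGACC from 2.55 ± 0.733 to 16.99 ± 4.84 (0.025) and GGGGCTGTGATGATTGCTTTCC from 0.299 ± 0.0678 to 4.74 ± 3.49 (0.026). The first was at 39.0 ± 7.80 CPM in G1. G2 against S gave 0 calls by edgeR (58 at an unadjusted p under 0.05, 0 by DESeq2 and 1 with the replicate number as a block), and G1 against M gave 0 (47 and 2 by DESeq2). M against G2 gave 14 calls with DESeq2, 5 within replicates 1 to 3 and 0 within replicates 4 and 5 (0 at an unadjusted p under 0.05), and 0 without any one of replicate numbers 1 to 4.

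In the AGO1 IP 19 of 19919 features were called over the 4 phases, of which 12 were highest in G1, 6 in S and 1 in G2. The one highest in G2 and 1 of those highest in S were over 100-fold higher in the IP than in total RNA and may not be of tobacco. TCTTGGCTTTGCAATGTTGGC, also called in total RNA, rose from 64.7 ± 40.8 CPM in G2 to 353 ± 70.5 in G1 (n = 5 each; adjusted p = 0.0089, edgeR quasi-likelihood test). TTCACCCCGCACGTCGAACGCG rose from 34.3 ± 12.6 to 102 ± 11.3 CPM (adjusted p = 0.010) and TAGGTCCATGACTAGTATGCT from 19.6 ± 11.7 to 66.2 ± 15.1 (adjusted p = 0.039). Each adjusted p is that of the test over the 4 phases, not of the lowest and highest phase printed. Both fractions called 2 tags in common. From S to G1 the first of these tags rose 3.18-fold in the IP within replicates 1 to 3 and 5.82-fold within replicates 4 and 5.

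**Figure D3:**
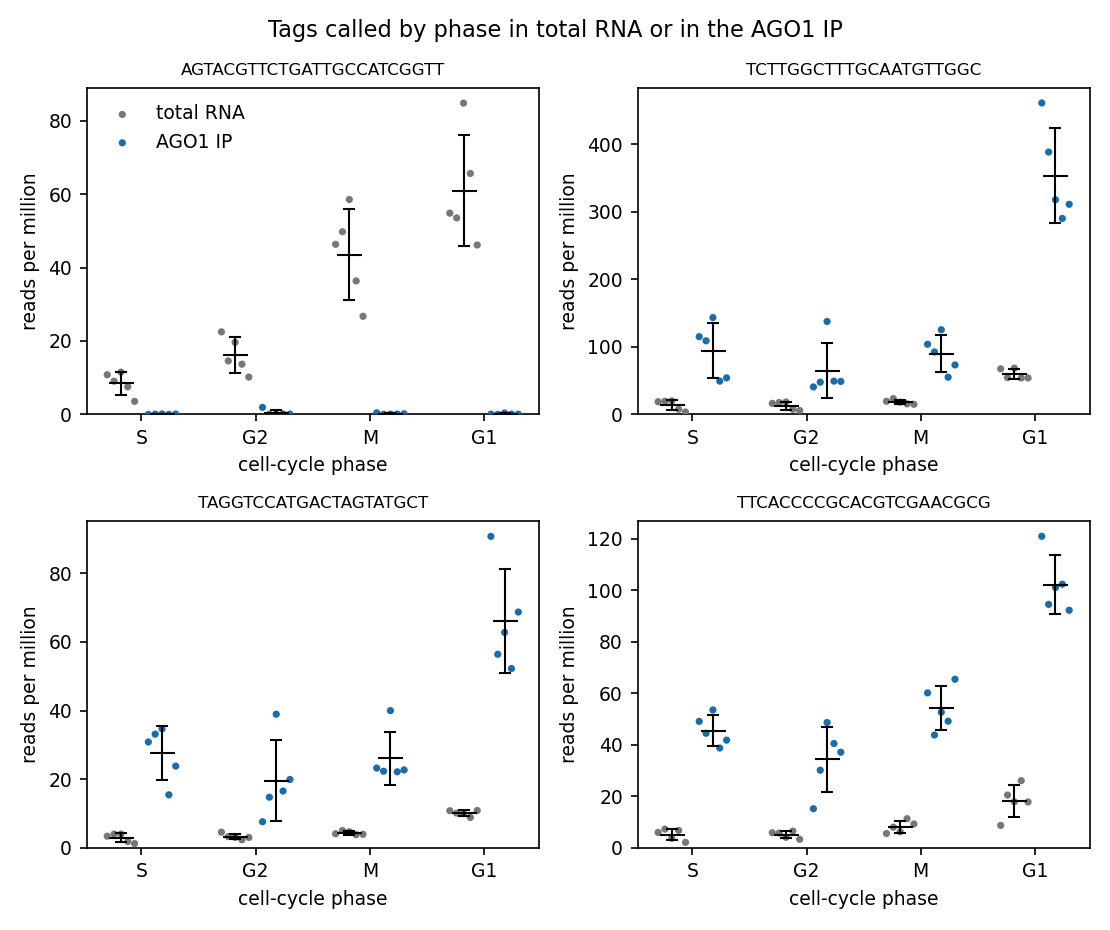
Level (CPM) of 4 tags in each library of total RNA (grey) and of the AGO1 IP (blue) by cell-cycle phase; bars give the mean and SD of 5 libraries, and each panel has its own scale. AGTACGTTCTGATTGCCATCGGTT reaches 61.0 in G1 of total RNA, and TCTTGGCTTTGCAATGTTGGC reaches 353 in G1 of the IP.

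Listed families did not pass the phase test over all features in the IP: 0 of 20 measured families were called by edgeR, 2 had an unadjusted p under 0.05 and DESeq2 called 1. Mean miR166 was 23945 ± 5841 CPM in S, 22867 ± 2146 in G2, 20304 ± 1728 in M and 12489 ± 4630 in G1 (adjusted p = 0.606 over all features, 0.033 adjusted over the list alone, 0.111 over all families, 0.0407 with DESeq2 and 0.0269 with the replicate number as a block). Mean miR398 was 5636 ± 1538 in S and 2601 ± 765 in G1 (adjusted p = 0.82, 0.051 adjusted over the list alone and 0.0079 with the replicate number as a block). With that block 2 of the 20 families were called by phase. The silencing machinery families gave no unadjusted p under 0.05, with miR168 at 3195 ± 788 CPM in S and 2923 ± 800 in G1. The tRNA-Ala start was at 6.37 ± 1.33 CPM in S and 25.2 ± 27.9 in G2 (adjusted p = 0.9999 over all features and 0.022 adjusted over the list alone), and the largest values in G2 came from the same shallow libraries as the low first U shares.

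Animal miRNA sequences, a control list, were at 819 CPM in the IP of M replicate 2, 315 in G1 replicate 2, 36.04 in G2 replicate 2 and 23.4 in G2 replicate 1, against 2.99 or less in each total RNA library. Without these 4 libraries 44 features were called by phase, 13 of them among the 19. Within replicates 1 to 3 0 of 17092 features were called (849 at an unadjusted p under 0.05), within replicates 4 and 5 8, and with a batch term 99. Leaving out replicate number 1, 4 or 5 left 0 calls (367, 536 and 619 at an unadjusted p under 0.05), number 3 left 1 and number 2 left 9, and 3 of 60 splits of the IP libraries, the real one among them, gave 19 calls or more. With the replicate number as a block, 177 features were called, all 19 among them.

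No neighbouring phases of the IP gave a call with edgeR. G2 against S gave 0 of 19919 (639 at an unadjusted p under 0.05; 88 with DESeq2), M against G2 gave 0 (440; 4 with DESeq2) and G1 against M gave 0 (145; 13 with DESeq2). With the replicate number as a block, G1 against M gave 9 calls, 8 higher and 1 lower in G1, and with a batch term it gave 7.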

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

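The tests of explanations for the 3 patterns in this part were chosen after the results were seen.

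Libraries far from the other 4 of their group were searched for by the gap to the nearest library over the range of the group. The search marked 6 of 56 groups, where about 1 in 20 is marked by chance. In total RNA, the share of 22-nt reads was 27.65% in G1 replicate 4 against 22.9% to 24.2% in the others, and the share of a first U was 21.44% in S replicate 5 against 25.8% to 26.8%. In the IP, M replicate 2 had 38.18% of 22-nt reads against 46.2% to 48.5% and 76.46% of a first U against 90.2% to 93.4%. G1 replicate 2 had 90.06% of a first U against 93.0% to 93.6%, and miR166 was at 26520 CPM in G2 replicate 4 against 21040 to 22630.

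Animal miRNA sequences, which no comparison used, were above their highest level in a total RNA library (2.99 CPM) in 7 IP libraries. They were at 819 CPM in M replicate 2 (95% interval 783 to 857, counting error only), 315.4 in G1 replicate 2 (305 to 326), 36.04 in G2 replicate 2, 23.45 in G2 replicate 1, 8.918 in S replicate 3, 3.289 in M replicate 4 and 3.217 in M replicate 1.

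The first pattern weighed was that tags called by phase in total RNA were highest in G1 or M. A rise of rRNA fragments in G1 was not seen for 5.8S rRNA, at 0.962% ± 0.291 of reads in G1 and 1.05% ± 0.720 in S (exact permutation test, p = 0.873). The median log2 ratio of the tags was 2.22. The S libraries include replicate 5, which had the highest share of 5.8S rRNA. Fragments of other rRNAs were not measured, so they remain possible. A shift of levels between replicates 1 to 3 and 4 and 5 was ruled out, since each phase holds the same numbers of both and 28 of the 31 tags stayed called with the batch as a term. A difference between phases in 1 batch only was weighed with the 27 tags called within replicates 1 to 3 alone. They went both ways, with 13 higher in G1 within replicates 1 to 3 and 14 within replicates 4 and 5. Their median log2 ratio of G1 over S within replicates 4 and 5, 0.0199, therefore decides nothing. Of them, 26 kept their direction in replicates 4 and 5, which took no part in their choice. This argues against a difference in 1 batch only for these 27 tags. The measure set for the test was the median, however, and the share of all tested tags that keep their direction was not counted. The 31 tags were all higher in G1 than in S in either batch, with lowest log2 ratios of 0.92 in replicates 1 to 3 and 1.33 in replicates 4 and 5. They were chosen from all replicates, however, so this is no separate test. RNA that differs with the phase stayed open, since 25 of the 31 called tags were higher in G1 than in S in the IP with a median log2 ratio of 0.29, many of them near 0 CPM there, while 6 of 6 that passed the filter of the IP fit and 7 of 7 IP-called tags that passed that of total RNA kept their direction, although a high level in G1 helps a tag to pass.

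The second pattern was a group of 231 tags that shared a stretch of 15 nt with the 5 tags of the largest rise in the IP, 103 of them tested, at 14070 ± 8289 CPM in the IP and 12.7 ± 9.10 in total RNA (n = 20 each). Loading by the first base, as for miRNAs, could not be ruled out by their ratio. With those 5 tags left out, the summed reads of the 86 tags without a first U had a log2 ratio of 9.68 and at least 9.01 in each phase. Tags without a first U outside the group had a median of −6.09. However, tags were kept only at 1 CPM or more in at least 5 libraries. The 86 tags held 4.58 CPM together in total RNA, so most could be kept only through the IP, which favoured a high ratio. The values show that tags of the group without a first U were present in the IP, at 3747 CPM together. RNA brought in with the immunoprecipitation could neither be ruled out nor shown, because the group was at 4.27 CPM or more in each total RNA library, a level that reads assigned to the wrong library could also give. No biological explanation was tested.

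The third pattern was a low share of a first U in the IP of G2 replicate 1 (58.6%), G2 replicate 2 (62.0%) and M replicate 2 (76.5%), against 90.1% to 93.6% in the other 17. Carry-over of total RNA was ruled out, since a mixture would hold 20.03%, 18.6% and 12.5% of 24-nt reads and these libraries held 7.24% at most. As for low depth, 3 of the 3 were the shallowest IP libraries. Counting error at their depth reached at most 0.0769 percentage points to either side, which argues against low read counts alone. Another cause that also lowered the depth was not tested and remained possible. RNA of another organism could not be told apart. The lowest animal miRNA level of the 3 libraries was 23.4 CPM, while G1 replicate 2 had 315 at a first U share of 90.1%. That share was the lowest of the other 17 libraries and was marked as low within its group. No biological explanation was tested.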

How the results depend on the processing

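A batch term, leaving out 4 IP libraries, leaving out S replicate 5 of total RNA, shares within batches and the paired test of shares were chosen after the results were seen. The differences in shares between IP and total RNA kept their direction in each alternative, although not always an adjusted p under 0.05. Counts of features called by phase ranged widely, whereas no listed family was called by phase in total RNA over all features in any alternative. Adjusted over the measured families alone, 1 of 17 passed without replicate 5. Over the alternatives, ratios of single listed small RNAs kept direction and side of the threshold in 498 cases, were weaker in 7, stronger in 4 and reversed in 10. The shallowest IP library held 1578049 reads of 18 to 28 nt, and at these library sizes simulated 4-fold changes were recovered for 71% to 89% of changed features in the IP phase fits and 47% to 69% in those of the deeper total RNA. Unless stated, the cause was not tested.

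Between IP and total RNA a filter at 1 CPM called 151384, as more features were tested, and replicates 4 and 5 alone called 25040 of fewer tested features. Phase dependence of this difference gave 538 with DESeq2 and 2 with the filter at 1 CPM. DESeq2 called 13 of the 20 families between IP and total RNA, and by phase in the IP it called 1 family and the replicate block 2. Adjusted over the measured families alone, the phase test in the IP passed 2 with DESeq2, 4 with the block and 1 without replicate 1. The log2 ratio of IP over total RNA reversed with DESeq2, whose size factors shift all ratios, to −0.0096 for miR156, −0.17 for miR167, −1.02 for miR168, −0.30 for miR393, −1.43 for miR397, −0.0379 for miR398, −0.10 for miR6019 and −1.96 for the passenger strand of miR390. That of the passenger strand also reversed to −0.45 with only replicates 1 to 3 and to −0.15 without replicate 4, and leaving out each replicate number in turn gave −0.15 to 0.60.

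By phase in total RNA (31 calls), library totals gave 52, DESeq2 91, the filter at 1 CPM 884, tags of 20 to 24 nt 202, and replicates 4 and 5 alone 0. M against G2 in total RNA (3 calls) gave 5 with library totals, 14 with DESeq2, 145 with the filter, 22 with tags of 20 to 24 nt, 5 with only replicates 1 to 3, 0 with only replicates 4 and 5, and 9 without S replicate 5. G1 against M in total RNA (0) gave 2 with DESeq2 and 2 with tags of 20 to 24 nt.

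By phase in the IP (19 calls), library totals gave 7, DESeq2 202, replicates 1 to 3 alone 0, replicates 4 and 5 alone 8, leaving out 4 IP libraries 44 and a batch term 99. DESeq2 gave 88 for G2 against S, 4 for M against G2 and 13 for G1 against M in the IP (0 each). M against G2 in the IP gave 2 with the filter at 1 CPM, and G1 against M gave 1 with only replicates 4 and 5, 1 without the 4 IP libraries and 7 with a batch term.

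With the replicate number as a block, counts were 138 by phase in total RNA, 1 for G2 against S, 16 for M against G2, 177 by phase in the IP and 9 for G1 against M in the IP. All 31 and all 19 calls of the fits without the block were among them. Leaving out each replicate number in turn, which lowers the number of libraries, gave 2 to 40 calls by phase in total RNA, 0 to 7 for M against G2 in total RNA, 0 to 9 by phase in the IP and 0 to 1 for G1 against M in the IP.

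Over distinct sequences, each counted once, the IP minus total RNA difference was 15.2 percentage points for 21 nt and −35.2 for 24 nt, and 1 test between neighbouring phases passed. In replicates 4 and 5 alone the 21-nt difference was 24.3. With any one replicate number left out, the exact test of the shares reached 0.0286 at best. None passed adjustment, since only the 16 tests of IP against total RNA had an unadjusted p under 0.05. Per reads of all lengths, 15 of the 16 tests of IP against total RNA passed.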

Other observations

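The grouping of tags by shared stretches, the count of a motif and the reading of the splits by replicate pairs were chosen after the results were seen.

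Tags that shared a stretch with called ones were also summed by set. The largest such set held 122 tags, which together were at 474 ± 124 CPM in S and 824 ± 86.4 in G1 of total RNA, and at 880 ± 95.9 and 1151 ± 267 in the IP (n = 5 each). Another set was at 51.7 ± 19.8 CPM in S and 160 ± 22.7 in G1 of total RNA. The set with TCTTGGCTTTGCAATGTTGGC was at 114 ± 45.6 CPM in S and 408 ± 75.6 in G1 of the IP. These sums were formed from tags already called and were not tested again. The passenger strands of miR166 and miR156, below the level called measured, were at 8.23 and 6.84 CPM in total RNA and 0.0575 and 0.734 in the IP, and that of miR396 at 3.69 and 5.49.

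Among IP tags called by phase that were not highest in G1, 3 of 7 held TGATGA within their first 14 nt, against 232 of 19883 other tested tags. The motif was noticed first in the same tags, so the counts are no test of it. TGATGA is the core of box C of C/D small nucleolar RNAs. GAGCTGTGATGAGATCTGGAGATA was at 9.87 CPM in S and 2.17 in G1, AGATGTGATGAACACATTTGGTCC at 10.96 and 3.34, and CTGCTGTGATGAATTCATGAAA at 8.19 and 3.14. GGGGCTGTGATGATTGCTTTCC, which also holds the motif there, went the other way in total RNA, from 0.392 CPM in S to 10.01 in G1. The group of 231 tags described above was at 17260 CPM in S, 18980 in G2, 11880 in M and 8163 in G1 of the IP.

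Whether few RNAs lie behind the tags called by phase stayed open without a genome. Of the 48 tags called in either fraction, 20 shared a stretch of 15 nt with another, against at most 10 in 1000 random sets. By this rule the 48 fell into 36 sets and the 31 called in total RNA into 25. Some tags of separate sets overlapped end to start by a shorter stretch, which the rule does not join. The counts of sets therefore do not show how many RNAs lie behind the tags.

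Other splits of the same libraries were used to ask how often a count as high as the real one arises without regard to the labels. For IP against total RNA 1 of 21 splits, the real one, reached 38207, and the highest other, at 28762, had exchanged the labels of 15 of the 20 IP libraries. For phase dependence 21 of 21 splits gave 0 calls or more, that is at least the real 0. By phase in total RNA 1 of 60 splits reached 31, the highest other being 1, and for M against G2 in total RNA 1 of 60 reached 3, the highest other being 0. By phase in the IP 3 of 60 splits reached 19, with 65 as the highest, so chance is not excluded for that count. These splits took no account of the replicate numbers, which pair the IP libraries. The fit with the number as a block called 177, all 19 among them, and was not run on other splits.

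The real count was 0 for G2 against S and G1 against M in total RNA and for the 3 neighbouring comparisons in the IP. All 60 of 60 splits reach 0 by necessity, so this decides nothing about chance. Of these, 1 split of G2 against S in total RNA called 5859, and 2 splits of M against G2 in the IP called up to 1831. Each set libraries with the same replicate number together and parted 1 pair only. Splits that parted all 5 pairs, as the real one does, gave no calls other than the real 3 for M against G2 in total RNA. There were only 8 of them per comparison, the real one included.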
